A study of Mus musculus with 6 samples.

How the data were processed

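RNA of vascular smooth muscle cells from the descending aorta of mouse embryos at embryonic day 14.5 had been sequenced in 6 libraries, 2 each of wildtype, heterozygous and knockout genotype for Jag1. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit and libraries were made from 500 ng of total RNA with the Illumina TruSeq RNA kit. Per the labels, the wildtype libraries had floxed alleles and no Cre, and the other 2 groups carried Cre, so Cre differed together with Jag1 in both comparisons against wildtype and not in knockout against heterozygous. The labels do not say that replicates came from separate animals or cultures, so every p value measures only the spread between samples. They also do not say which exons were deleted or the sex of the embryos.

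The deposited table held 37309 Ensembl genes, and 314 gene symbols were used by more than 1 of them. Its signal values per library were read counts per gene that the authors had divided by 1 size factor per library: each library's deposited values were whole multiples of a single step to within 0.001 of a read, and dividing by that step gave the reads back. The deposited RPKM values were means of the 2 scaled values of a group divided by gene length and by 1 common total. The deposited log2 ratios were those of the authors and ran in the reverse order of their names, checked against the scaled values, and were turned here. The deposited p-values and adjusted p-values were those of the authors' own comparisons and were used here only for a count of shared calls and for Sox9. Per the submitters' processing notes, TopHat2 2.0.4, HTSeq 0.5.4p3, DESeq 1.16.0 and the genome build mm9 were used; the notes give no roles for these tools, no strand setting and no annotation release. Genes with near-identical copies or with overlapping or antisense partners are therefore uncertain, among them the Y-linked genes and their X-linked partners, the Prl2c family, Lyz1 and Lyz2, Xist and Tsix, and Rps2. No coordinates were used, because the reference available here is of another build.

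The recovered reads in genes were 28123670 and 20561009 in the wildtype libraries, 23384791 and 17939989 in the heterozygous libraries and 24555472 and 17323962 in the knockout libraries, and 1 read was worth 0.774 to 1.22 scaled units. The 10 most abundant genes held 8.83% to 9.68% of the scaled values and mitochondrial transcripts 3.15% to 3.68%. The scatter between the 2 libraries of a group, as chi-square per gene over counting error for genes with 20 or more summed reads, was 5.07 in wildtype, 3.75 in heterozygous and 23.5 in knockout. Ratios of genes with 1 to 3 reads in a group are given with an exact 95% interval for counting error.

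Groups, tests, gene lists, the rule for named genes and the alternatives were set before the data were examined. Genes with a scaled value of 10 or more in at least 2 of the 6 libraries (15781) were tested on log2(value + 1) with limma 3.58.1, with a mean trend in the variance prior and all 6 libraries in 1 fit (3 residual and 6.17 prior degrees of freedom). P values were adjusted by the Benjamini-Hochberg method, and genes passed at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. With 2 libraries per group the former had little power, so a list that did not pass with it is not shown to be unchanged. Camera compares a list with the other genes, whereas fry tests whether its genes move 1 way on balance against no change, so a range of adjusted p over the alternatives of a list holds both kinds of test. Counts of members adjusted over the list alone are given too. The 27 lists, fixed from knowledge of the tissue and the series title, held chondrogenic transcription factors, cartilage matrix, hypertrophic cartilage and bone, tendon and sclerotome, contractile smooth muscle, Notch targets, Notch ligands, receptors and modifiers, elastic fibre, interstitial collagens and small proteoglycans, TGF-beta and BMP signalling, Hedgehog signalling, Wnt signalling, proliferation, immediate early genes, hypoxia and glycolysis, interferon response, and Hox, sex-linked, ribosomal protein and mitochondrial genes. The others held markers of endothelial, erythroid, macrophage and leukocyte, neural and Schwann, fibroblast and adventitial, skeletal and cardiac muscle cells, and of epithelial, lung, mesothelial and adipose cells. Erythroid markers had 3 measured members, under the 5 required, and were not tested.

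The named genes are Jag1 and Sox9, and in each comparison the 10 highest and 10 lowest log2 changes among genes that passed, whose groups did not overlap, whose higher group had a mean of 50 or more and whose symbol was not a predicted model. Up to 4 members of each list with the smallest p were added, and any further member that passed could be named. Sex-linked genes are reported with their list, and some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Genes are said to follow the leukocyte markers if 2 log2 ratios both lay within the span of 19 leukocyte list members. The span was -2.78 to -1.42 in knockout over heterozygous and -0.40 to 1.55 in heterozygous over wildtype. There were 463 such genes, and this grouping was chosen after the values were seen. Cx3cr1 alone set the ends of -1.42 and -0.40, while the median of the 19 in heterozygous over wildtype was 0.87. The grouping thus also holds genes without a rise there: 212 of the 463 passed as higher in heterozygous over wildtype.

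Alternatives were pseudocounts of 0.5 and 8, no filter, a mean of 50 or more, TMM factors, quantile normalization, limma without the mean trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, only the 2 groups compared, an adjusted p under 0.10, the replicate number as a block, and each library left out in turn. A fit with a library left out holds 1 library of that group, so its p values rest on the spread within the other groups alone. Tests without genes on chromosomes X and Y and without genes that follow the leukocyte markers were chosen after seeing the data. The replicate numbers come from the sample titles, which do not say what a number marks; libraries numbered 1 were deeper than those numbered 2 in every group. Deviations of same-numbered libraries from their group means correlated at 0.168 (wildtype and heterozygous), 0.199 (wildtype and knockout) and 0.139 (heterozygous and knockout), all over the 0.1 set as the bound, so the numbers were taken to pair the libraries. The main fit, set beforehand, did not use this pairing, which entered only as the block alternative. Depth ran with the number too, so pairing and depth cannot be told apart. Tested on simulated data with 200 planted genes, limma recovered 38.8% of those with a 1.5-fold and 94% of those with a 2-fold change. None had the wrong sign, and 15 false calls were made among 15719 genes. The simulated data had 2 libraries per group as here, but the same scatter per gene in every group. The real knockout pair scattered more (chi-square per gene 23.5 against 5.07 and 3.75), so these rates do not bound errors in the knockout comparisons. Shared responses were set beside 50 simulations of unchanged groups. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.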

Results

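RNA was sequenced from vascular smooth muscle cells of the descending aorta of mouse embryos at embryonic day 14.5. Jag1 encodes a transmembrane ligand of the Notch receptors. The 6 libraries formed 3 groups of 2: wildtype libraries from animals with floxed Jag1 and no Cre recombinase, heterozygous libraries with 1 floxed allele and Cre, and knockout libraries with both alleles floxed and Cre. Across genes, which are not independent replicates, the log2 values of the 2 libraries of a group correlated at r = 0.994 in wildtype, 0.993 in heterozygous and 0.985 in knockout, and every library correlated best with the other library of its group. Values are scaled read counts as mean ± SD over the 2 libraries of a group, log2 changes are given ± SE, and adjusted p values come from limma.

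Jag1 (ENSMUSG00000027276, chromosome 2 of mm9) was measured first because it is the deleted gene. Its scaled read counts were 1965 and 1885 in the wildtype libraries, 492 and 584 in the heterozygous libraries, and 19.9 and 35.4 in the knockout libraries, where they came from 22 and 29 reads. The heterozygous level was 28% of wildtype, a log2 change of -1.84 ± 0.23 (adjusted p = 0.00129), and the knockout level was 1.44% of wildtype, a log2 change of -6.12 ± 0.23 (adjusted p = 1.40e-06). Knockout over heterozygous was -4.28 ± 0.23 (adjusted p = 3.91e-06). Jag1 was thus lower in both libraries of each group with Cre, though the labels do not state which exons were deleted and only totals per gene were deposited.

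The comparison of knockout with wildtype asked what aortic smooth muscle cells transcribe without Jag1, with cartilage genes singled out by the series title. In the knockout libraries, 9 of 20 cartilage matrix genes rose and 3 fell, and 19 of 39 contractile genes fell and 2 rose. With an estimated correlation neither list passed (adjusted p = 0.343 and 0.673). Comp, a cartilage matrix protein, rose from 5.85 ± 0.603 to 127 ± 16.8 (log2 change 4.22 ± 0.24, n = 2 per group), and Col2a1, the main collagen of cartilage, rose from 61.3 ± 0.922 to 254 ± 25.5 (2.03 ± 0.16). Des, the muscle intermediate filament protein desmin, fell from 5409 ± 440 to 869 ± 77.6 (-2.64 ± 0.10). Sox9 (ENSMUSG00000000567, chromosome 11), the transcription factor required for cartilage formation, measured 464 and 268 in the knockout libraries against 231 and 236 in wildtype and did not pass (0.59 ± 0.22, adjusted p = 0.135). Sox9 had a log2 change of 0.19 (adjusted p = 0.405) without knockout replicate 1 and of 0.99 (2.60e-06) without knockout replicate 2, but the latter fit held 1 knockout library, so its p rests on the spread within the other groups alone, and 5613 genes passed in it. Over its 19 alternatives, that fit included, the adjusted p ran from 2.60e-06 to 0.415.

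**Figure D1:**
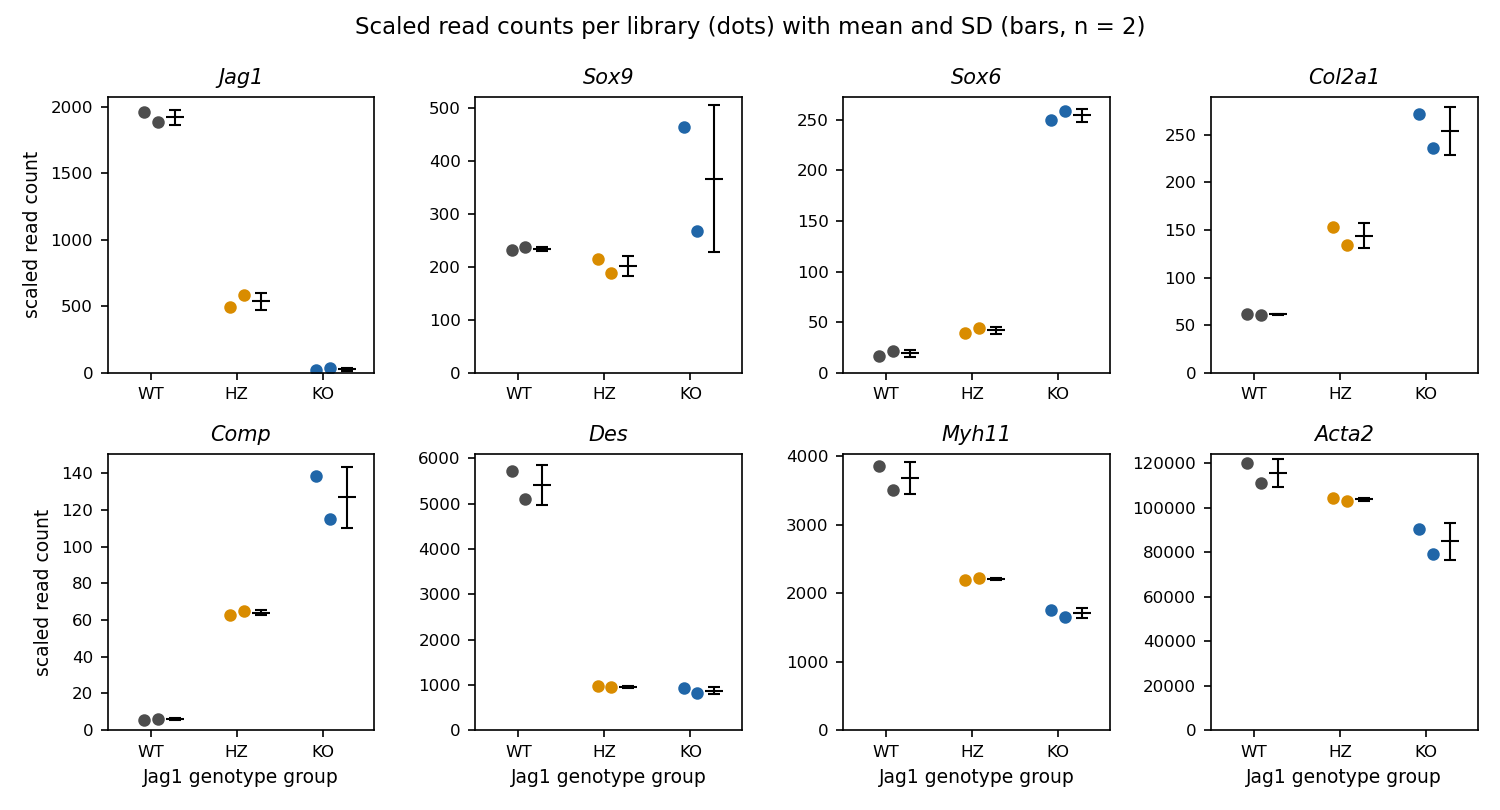
Scaled read counts of 8 genes in each library (dots; y axis from 0), by genotype group on the x axis (WT wildtype, HZ heterozygous, KO knockout), with bars for mean and SD (n = 2). Jag1 fell from 1925 in wildtype to 27.7 in knockout, Comp and Col2a1 rose to 127 and 254, and Sox9 lay at 464 and 268 in the 2 knockout libraries.

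Of 19 measured chondrogenic transcription factors, 6 rose, 1 fell and 12 did not pass in knockout against wildtype (9 rose and 2 fell adjusted over the list alone). The list's median log2 change was 0.33 (camera adjusted p = 0.00176, and adjusted p = 0.712 with an estimated correlation). Sox6, which acts with Sox9 in chondrocytes, rose from 19.5 ± 3.48 to 255 ± 6.31 (3.65 ± 0.21), and Pax1, a sclerotome regulator, Runx3 and Foxc1 rose by 1.49 ± 0.17, 2.19 ± 0.34 and 0.85 ± 0.12. The camera call was lost without knockout replicate 1 (adjusted p = 0.0944), and over 13 alternatives its adjusted p ran from 0.000147 to 0.712. Of 20 cartilage matrix genes, 9 rose, 3 fell and 8 did not pass (11 and 3 adjusted over the list alone). The median was 0.51 (camera adjusted p = 0.000378, and adjusted p = 0.343 with an estimated correlation). Prg4, which encodes the joint lubricant lubricin, rose from 252 ± 9.04 to 1431 ± 638, Matn3 by 2.06 ± 0.24, Pcolce2 by 1.43 ± 0.13, Prelp by 1.25 ± 0.19 and Fmod by 1.13 ± 0.16. Acan, the aggrecan core protein, chosen here after the values were seen, measured 17 ± 7.74 in wildtype and 18.8 ± 4.15 in knockout (0.20 ± 0.38, adjusted p = 0.801), with a log2 change of -0.02 without knockout replicate 1 and -0.26 without wildtype replicate 2. Its adjusted p ran from 0.442 to 0.983 over 18 alternatives.

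Of 13 genes of hypertrophic cartilage and bone, 4 rose, 2 fell and 7 did not pass in the knockout libraries (6 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.120). Spp1, which encodes osteopontin, rose from 20212 ± 1349 to 52893 ± 2732, and the bone regulators Sp7 and Dlx5 rose by 2.66 ± 0.25 and 2.03 ± 0.32. Col10a1, the collagen of hypertrophic cartilage, fell from 1472 ± 118 to 425 ± 50.2, and Mmp9, a matrix protease that leukocytes also transcribe, fell by 3.60 on the log2 scale, which was -4.64 without knockout replicate 1 and -2.56 without knockout replicate 2. Of 10 tendon and sclerotome genes, 2 rose, 2 fell and 6 did not pass (3 and 3 adjusted over the list alone, median -0.05, camera adjusted p = 0.869). The tendon regulators Scx and Mkx rose by 2.35 ± 0.24 and 0.99 ± 0.16, while Tnmd and Egr2 changed by -1.41 ± 0.22 and -1.39 ± 0.20.

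Of 39 contractile smooth muscle genes, 2 rose, 19 fell and 18 did not pass in knockout against wildtype (4 and 22 adjusted over the list alone). The median was -0.45 (camera adjusted p = 3.03e-08, and adjusted p = 0.673 with an estimated correlation). The smooth muscle myosin Myh11 fell from 3682 ± 240 to 1705 ± 73.5 (-1.11 ± 0.09), and Actg2, Mylk, Kcnmb1 and Cnn1 changed by -1.72 ± 0.08, -1.37 ± 0.10, -2.38 ± 0.20 and -0.77 ± 0.09. Sncg rose by 2.17 ± 0.24. Acta2, the most abundant smooth muscle actin, fell from 115657 ± 6395 to 84888 ± 8224 (-0.45 ± 0.10, adjusted p = 0.0188). The call on Acta2 was lost without wildtype replicate 1 (adjusted p = 0.208), wildtype replicate 2 (0.1003), heterozygous replicate 1 (0.0625) or heterozygous replicate 2 (0.0625). It was also lost with no filter on low values (0.0974), without the mean trend (0.0775) and with only the 2 groups compared (0.0629), and over 19 alternatives its adjusted p ran from 7.48e-05 to 0.208. Of 24 elastic fibre genes, 5 rose, 5 fell and 14 did not pass (6 and 7 adjusted over the list alone, median -0.05, camera adjusted p = 0.686). The crosslinking enzyme Loxl2 fell from 28994 ± 216 to 6476 ± 249 and fibrillin Fbn1 from 32197 ± 1364 to 17768 ± 416, and Efemp1 rose by 1.90 ± 0.08. Of 33 interstitial collagens and small proteoglycans, 4 rose, 14 fell and 15 did not pass (6 and 20 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.000131, and adjusted p = 0.673 with an estimated correlation). Postn and Col15a1 changed by -1.85 ± 0.09 and -2.28 ± 0.12, Col3a1 fell by 1.00, and Col8a2 rose by 2.15 ± 0.17. Leukocyte transcripts fell in the same comparison, and 4 of the 14 lower collagen and proteoglycan genes had ratios in both steps between groups that lay within the span of the leukocyte markers.

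Of 13 Notch targets, 1 rose, 1 fell and 11 did not pass in the knockout libraries (1 and 1 adjusted over the list alone, median 0.05, mean -0.11, camera direction up, adjusted p = 0.811). Heyl, a Notch effector of smooth muscle, fell from 17.1 ± 2.36 to 2.74 ± 1.31 (-2.32 ± 0.60, adjusted p = 0.0339), and Ccnd1, the cyclin of cell cycle entry, rose from 4440 ± 22.8 to 9583 ± 492. Hes1, chosen after the values were seen, measured 1121 ± 10.2 and 1178 ± 176 (0.06 ± 0.11, adjusted p = 0.789, with -0.09 without knockout replicate 1 and adjusted p from 0.0683 to 0.930 over 19 alternatives). The call on Heyl was lost without knockout replicate 1 (adjusted p = 0.0724), wildtype replicate 1 (0.188) or wildtype replicate 2 (0.265), with quantile normalization (0.0529) and with DESeq2 (0.104), and its adjusted p ran from 0.0114 to 0.265 over 18 alternatives. Of 30 Notch ligands, receptors and modifiers, 2 rose, 1 fell and 27 did not pass (2 and 1 adjusted over the list alone, mean -0.04, camera direction up, adjusted p = 0.869). The 1 that fell was Jag1, the deleted gene, which is a member of this list and lowers its mean. Dlk1, a membrane protein related to the Notch ligands, rose from 197 ± 12.0 to 2536 ± 470 (3.67 ± 0.14). Of 36 genes of TGF-beta and BMP signalling, 8 rose, 4 fell and 24 did not pass (11 and 7 adjusted over the list alone, median 0.05, camera adjusted p = 0.387). Smad9 rose by 1.09 ± 0.10 and the BMP antagonist Nog by 1.60 ± 0.20, and the ligand Gdf6 changed by -1.25 ± 0.16. In Hedgehog signalling 1 of 10 genes rose, the co-receptor Boc (0.89 ± 0.11), and 9 did not pass (2 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.0786, with 0.00435 without knockout replicate 2 and 0.0238 without wildtype replicate 1 in a range of 0.00435 to 0.888). In Wnt signalling 6 of 25 genes rose, 5 fell and 14 did not pass (8 and 6 adjusted over the list alone, median 0.14, camera adjusted p = 0.449), with the receptor Lgr6 at 2.05 ± 0.19 and Wisp1 at -0.86 ± 0.09.

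Of 34 proliferation genes, 15 rose, 0 fell and 19 did not pass in knockout against wildtype (27 and 0 adjusted over the list alone). The median was 0.37 (camera adjusted p = 2.22e-12, and adjusted p = 0.0722 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.68 ± 0.09 and the replication helicase subunit Mcm4 by 0.60 ± 0.09. Of 24 hypoxia and glycolysis genes, 4 fell and 20 did not pass (7 fell adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0151, and adjusted p = 0.712 with an estimated correlation). Vegfa, the endothelial growth factor, fell from 5548 ± 14.9 to 1981 ± 126 and Egln3 from 295 ± 23.4 to 119 ± 12.5. The hypoxia call was lost without knockout replicate 2 (adjusted p = 0.0916) and its adjusted p ran from 0.00717 to 0.712 over 13 alternatives. Of 27 immediate early genes, 5 fell and 22 did not pass (5 fell adjusted over the list alone, median -0.08, camera adjusted p = 0.0920). That list passed without knockout replicate 1 (1.30e-06) and without wildtype replicate 2 (0.0118), turned direction without knockout replicate 2 (0.632), and ran from 1.30e-06 to 0.888 over 13 alternatives.

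Markers of other cell types also differed between knockout and wildtype. Of 22 macrophage and leukocyte markers, 21 fell and 1 did not pass (21 fell adjusted over the list alone). The median was -1.39 (camera adjusted p = 1.25e-23, and adjusted p = 0.0722 with an estimated correlation). Lysozyme Lyz2 fell from 16421 ± 719 to 6937 ± 287, and C1qa, Csf1r and Mrc1 changed by -1.71 ± 0.19, -1.03 ± 0.09 and -1.23 ± 0.10. Of 20 interferon response genes, 15 fell and 5 did not pass (17 fell adjusted over the list alone). The median was -1.05 (camera adjusted p = 2.16e-13, and adjusted p = 0.115 with an estimated correlation). Isg15, Usp18 and Oasl2 changed by -1.72 ± 0.15, -1.98 ± 0.18 and -1.27 ± 0.17, and 7 of the 15 lower interferon genes followed the leukocyte markers in both steps. Of the 1121 genes that fell, 332 (29.6%) followed them, which did not require a rise in heterozygous over wildtype. Among 16 endothelial markers, 1 rose, 5 fell and 10 did not pass (2 and 5 adjusted over the list alone, median 0.09, mean -0.40, camera direction down, adjusted p = 0.396). The receptor Kdr rose by 1.57 ± 0.12, while Flt1 fell from 3408 ± 6.31 to 615 ± 63.9 and Emcn from 172 ± 0.305 to 10 ± 1.37. Among 10 neural and Schwann cell markers, 3 rose, 1 fell and 6 did not pass (3 and 2 adjusted over the list alone, median -0.26, mean 0.34, camera direction up, adjusted p = 0.677), with Stmn2 up from 66.5 ± 2.34 to 594 ± 43.9. Among 18 fibroblast and adventitial markers, 4 rose, 4 fell and 10 did not pass (4 and 4 adjusted over the list alone, median -0.01, camera adjusted p = 0.996), with Pdgfra up by 1.88 ± 0.11. Among 15 epithelial, lung, mesothelial and adipose markers, 4 rose, 4 fell and 7 did not pass (4 and 6 adjusted over the list alone, median 0.01, mean -0.04, camera direction down, adjusted p = 0.709), with the mesothelial regulator Wt1 at -1.27 ± 0.16.

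Transcripts of the Y chromosome were nearly missing from both knockout libraries. Ddx3y measured 1155 ± 74.2 in wildtype, 986 ± 18.2 in heterozygous and 8.83 ± 4.8 in knockout, and Eif2s3y and Uty changed by -7.51 ± 0.19 and -6.00 ± 0.24 in knockout against wildtype. Kdm5d had 2 reads in the knockout libraries, 0.455% of its wildtype level (exact 95% interval 0.0550% to 1.65%, counting error only). Xist, transcribed from the inactive X chromosome of females, rose from 3385 ± 78.1 to 5704 ± 115 (0.75 ± 0.10). Of 10 sex-linked markers, 3 rose, 4 fell and 3 did not pass (3 and 4 adjusted over the list alone, median 0.16, mean -2.47, camera direction down, adjusted p = 0.239, with 0.0233 without knockout replicate 1 and 0.0497 without knockout replicate 2 in a range of 0.00196, from fry, to 0.888 over 13 alternatives). On chromosome X, 40 of 660 genes rose and 32 fell, with a median of 0.01.

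The 10 largest increases of the naming rule in knockout over wildtype included the transcription factors Irx3 (14.8 ± 1.23 to 322 ± 139, 4.29 ± 0.28), Irx5 (3.72 ± 0.24) and Six2 (3.05 ± 0.33), the integrin Itgb6 (4.2 ± 0.34), coagulation factor F5 (3.33 ± 0.31) and the retinoic acid binding protein Crabp1 (2.75 ± 0.25). Besides Jag1, the Y-linked genes and those given above, the 10 largest decreases held the cytokine Il1a, whose 3 knockout reads were 2.93% of its wildtype level (exact 95% interval 0.595% to 8.76%, counting error only), and Hoxc10 (-2.84 ± 0.38). Of 24 Hox genes, 5 rose, 2 fell and 17 did not pass (10 and 4 adjusted over the list alone, median 0.12, camera adjusted p = 0.0917, with 5.46e-05 without knockout replicate 2, a turned direction without knockout replicate 1 at 0.970, and a range of 5.46e-05 to 0.970 over 13 alternatives). Of 5 skeletal and cardiac muscle markers 1 fell and 4 did not pass (1 adjusted over the list alone, median -0.74, camera adjusted p = 0.0920, with 0.0197 without wildtype replicate 2 in a range of 0.0197 to 0.806). The 32 ribosomal protein genes and 13 mitochondrial transcripts did not pass (camera adjusted p = 0.869 and 0.622, medians -0.05 and 0.04).

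In total 1977 of 15781 genes passed in knockout against wildtype, 856 higher and 1121 lower, of which 291 and 521 changed at least 2-fold (unadjusted p under 0.05 for 3930). With the heterozygous libraries out of the fit, 1367 passed. The main fit shared its spread over the 3 groups, of which the knockout pair scattered most, so the counts do not rank the comparisons. The 2 groups were apart in 50.1% of genes, where chance gives 33.3% if the 4 libraries are exchangeable, which pairing by replicate number would make inexact. The authors' deposited table listed 1615 genes at an adjusted p under 0.05, and 1595 of their 1612 among the genes tested here were shared. The count was 3247 without knockout replicate 1, 5613 without knockout replicate 2, 865 without wildtype replicate 1 and 889 without wildtype replicate 2. Cre was present only in the knockout libraries of this pair, and 2 alternatives chosen after seeing the data gave 1541 genes without the genes that followed the leukocyte markers and 1902 (816 higher) without chromosomes X and Y. The genes that followed the leukocyte markers are defined by these same ratios, so the balance of higher and lower calls without them is no test in any comparison.

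**Figure D2:**
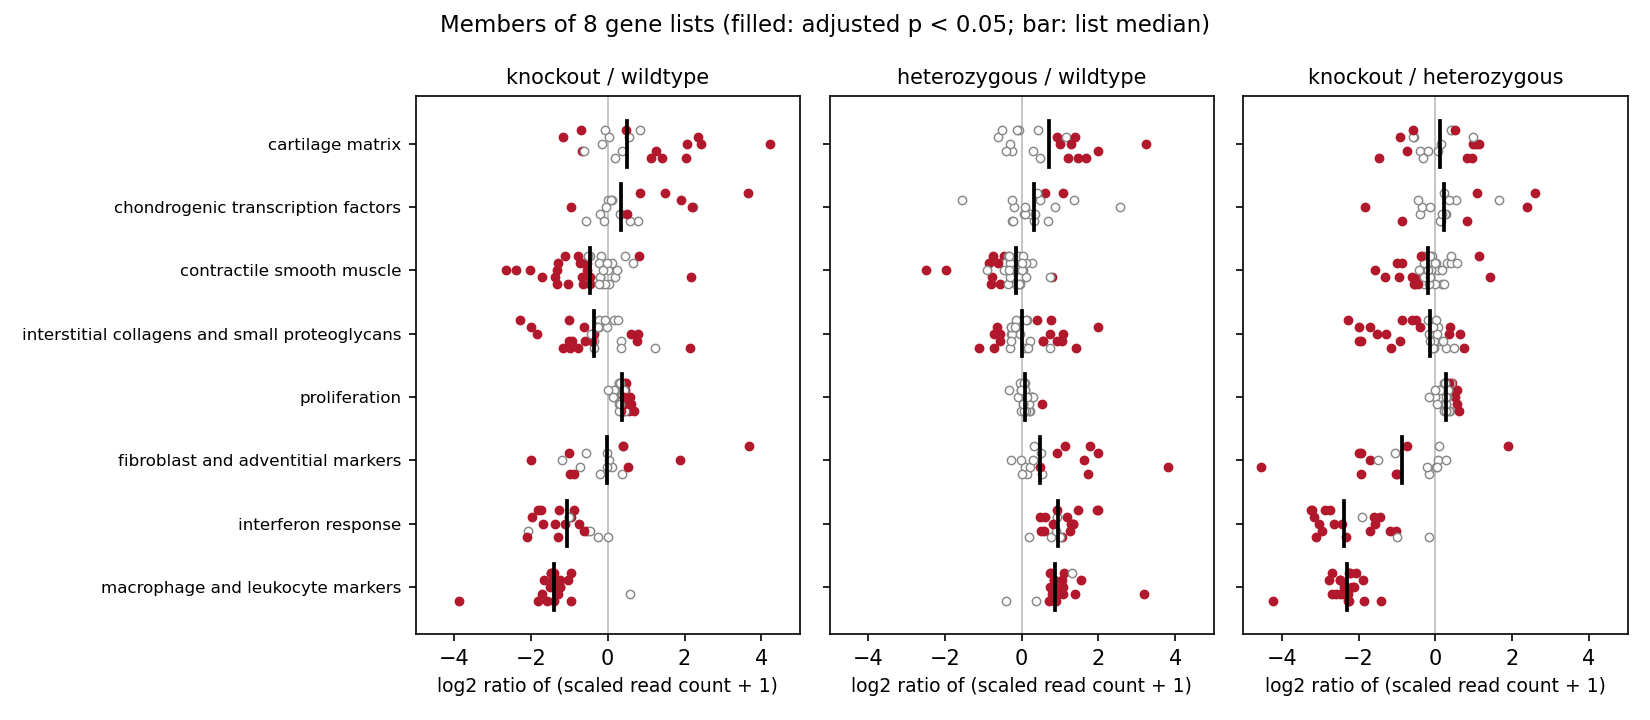
Log2 ratios of scaled read count + 1 (x axis) for the members of 8 gene lists (y axis) in the 3 comparisons; filled dots passed the adjusted p threshold, open dots did not, and black bars are list medians. The leukocyte list had medians of -1.39, 0.87 and -2.31, and the contractile list -0.45, -0.16 and -0.21.

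The comparison of heterozygous with wildtype asked what changes with the loss of 1 Jag1 allele. In the heterozygous libraries 9 of 20 cartilage matrix genes, 8 of 18 fibroblast markers, 19 of 22 leukocyte markers and 15 of 20 interferon genes rose, and 9 of 39 contractile genes fell. With an estimated correlation none of these lists passed (adjusted p = 0.214, 0.214, 0.127, 0.127 and 0.480). Comp rose from 5.85 ± 0.603 to 63.9 ± 1.40 (3.25 ± 0.24, n = 2 per group), Igf2, a fetal growth factor, from 1785 ± 15.2 to 11719 ± 225 (2.71 ± 0.17), and Des fell from 5409 ± 440 to 959 ± 21.6 (-2.49 ± 0.10). Sox9 measured 201 ± 19 against 234 ± 3.37 and did not pass (-0.22 ± 0.22, adjusted p = 0.731).

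Of 20 cartilage matrix genes, 9 rose, 0 fell and 11 did not pass in heterozygous against wildtype (11 and 1 adjusted over the list alone). The median was 0.71 (camera adjusted p = 0.000286, and adjusted p = 0.214 with an estimated correlation). Prelp and Fmod, small proteoglycans of cartilage and tendon, rose by 1.99 ± 0.19 and 1.47 ± 0.16 and Col2a1 by 1.22 ± 0.16. Acan rose from 17 ± 7.74 to 54.2 ± 13.7 (1.67 ± 0.38, adjusted p = 0.0258), a call lost without heterozygous replicate 1 (adjusted p = 0.279), heterozygous replicate 2 (0.114) or wildtype replicate 2 (0.230) and without the mean trend (0.0677), in a range of 0.000158 to 0.279 over 18 alternatives. Of 19 chondrogenic transcription factors, 2 rose and 17 did not pass (5 rose adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.0354, and adjusted p = 0.723 with an estimated correlation). That call was lost without heterozygous replicate 2 (adjusted p = 0.141) or wildtype replicate 2 (0.0660), in a range of 0.0139 to 0.723 over 13 alternatives. The 2 were Sox6 (1.07 ± 0.21) and Foxc1 (0.62 ± 0.12). Sox6 did not pass without heterozygous replicate 1 (adjusted p = 0.0913), heterozygous replicate 2 (0.152) or wildtype replicate 1 (0.136), in a range of 0.00106 to 0.152 over 19 alternatives. Foxc1 did not pass without heterozygous replicate 1 (0.131), heterozygous replicate 2 (0.174), wildtype replicate 1 (0.120) or wildtype replicate 2 (0.146), nor without the mean trend (0.0871), in a range of 1.04e-07 to 0.174. Of 13 genes of hypertrophic cartilage and bone, 6 rose, 1 fell and 6 did not pass (6 and 1 adjusted over the list alone). The median was 0.82 (camera adjusted p = 0.000407, and adjusted p = 0.214 with an estimated correlation). Mgp, an inhibitor of calcification, rose from 23605 ± 3.88 to 50870 ± 2753, the collagenase Mmp13 by 1.67 ± 0.15 and Spp1 by 0.98 ± 0.10. Of 10 tendon and sclerotome genes 2 rose and 8 did not pass (2 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.494).

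Of 39 contractile smooth muscle genes, 1 rose, 9 fell and 29 did not pass in the heterozygous libraries (2 and 14 adjusted over the list alone). The median was -0.16 (camera adjusted p = 1.01e-06, and adjusted p = 0.480 with an estimated correlation). Kcnmb1, Actg2 and Myh11 changed by -1.97 ± 0.20, -0.77 ± 0.08 and -0.74 ± 0.09, while Mylk, chosen here after the values were seen, measured 4886 ± 57.8 against 5055 ± 114 in wildtype (-0.05 ± 0.10, adjusted p = 0.894). Of 18 fibroblast and adventitial markers, 8 rose and 10 did not pass (10 rose adjusted over the list alone). The median was 0.49 (camera adjusted p = 3.35e-08, and adjusted p = 0.214 with an estimated correlation). Pdgfra rose from 444 ± 23.1 to 1360 ± 89.9 and Dpt by 1.73 ± 0.16. The proteoglycans Lum and Dcn, which this list shares with the collagen list, rose by 1.99 ± 0.14 and 0.92 ± 0.11. Of 33 interstitial collagens and small proteoglycans, 10 rose, 6 fell and 17 did not pass (10 and 9 adjusted over the list alone, median 0.01, camera adjusted p = 0.852), with Col8a2 up by 1.41 ± 0.17. Of 24 elastic fibre genes, 6 rose, 4 fell and 14 did not pass (7 and 5 adjusted over the list alone, median 0.14, camera adjusted p = 0.138). Fbln1 and Mfap4 rose by 1.40 ± 0.13 and 1.19 ± 0.15, and Loxl2 fell from 28994 ± 216 to 9990 ± 293. The elastic fibre list passed without knockout replicate 1 (adjusted p = 0.0475) or knockout replicate 2 (0.0486), in a range of 0.0374 to 0.723 over 13 alternatives.

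Of 13 Notch targets, 1 rose, 2 fell and 10 did not pass in heterozygous against wildtype (1 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 0.236). Hey2 fell from 87.5 ± 7.76 to 39.0 ± 4.17 (-1.15 ± 0.21, adjusted p = 0.00969) and Heyl from 17.1 ± 2.36 to 1.97 ± 1.09 (-2.66 ± 0.60, adjusted p = 0.0262). In knockout against wildtype Heyl was the only target that fell, so Hey2 did not pass there. Hey2 did not pass without heterozygous replicate 1 (adjusted p = 0.0712), heterozygous replicate 2 (0.119), wildtype replicate 1 (0.0773) or wildtype replicate 2 (0.135), in a range of 7.58e-05 to 0.135 over 19 alternatives. Heyl did not pass without heterozygous replicate 1 (0.0851), heterozygous replicate 2 (0.179), wildtype replicate 1 (0.188) or wildtype replicate 2 (0.264), in a range of 0.00154 to 0.264 over 17 alternatives. Of 30 Notch ligands, receptors and modifiers, 3 rose, 1 fell and 26 did not pass (5 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0652, with 0.0490 without wildtype replicate 1 in a range of 0.0374 to 0.671 over 13 alternatives), and Dlk1 rose from 197 ± 12.0 to 680 ± 45.6. The 1 ligand, receptor or modifier that fell was again Jag1 itself. Of 25 Wnt signalling genes, 10 rose, 4 fell and 11 did not pass (11 and 5 adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.0281, and adjusted p = 0.671 with an estimated correlation). The Wnt antagonist Sfrp1 and the ligand Wnt16 rose by 1.17 ± 0.10 and 1.78 ± 0.21, and Wnt5a and Wisp1 changed by -0.85 ± 0.09 and -0.74 ± 0.09. In TGF-beta and BMP signalling 6 of 36 genes rose, 3 fell and 27 did not pass (9 and 4 adjusted over the list alone, median 0.05, camera adjusted p = 0.214), with Bmp4 up by 1.23 ± 0.14. In Hedgehog signalling 1 of 10 genes rose and 9 did not pass (1 adjusted over the list alone, median 0.23, camera adjusted p = 0.0652). With the replicate number as a block the Hedgehog list passed (adjusted p = 0.0496), as it did without knockout replicate 1 (0.0475), knockout replicate 2 (0.0486) or wildtype replicate 1 (0.0225), in a range of 0.0225 to 0.723 over 13 alternatives. Of 24 hypoxia and glycolysis genes 4 fell and 20 did not pass (1 rose and 4 fell adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0192, and adjusted p = 0.653 with an estimated correlation). Vegfa fell by 0.81 on the log2 scale, and the list's call was lost without heterozygous replicate 2 (adjusted p = 0.141), in a range of 0.00281 to 0.653. Of 34 proliferation genes 1 rose and 33 did not pass (1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0652), and of 27 immediate early genes 2 rose and 25 did not pass (2 adjusted over the list alone, median 0.09, camera adjusted p = 0.460).

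Of 22 macrophage and leukocyte markers, 19 rose and 3 did not pass in the heterozygous libraries (20 rose adjusted over the list alone). The median was 0.87 (camera adjusted p = 1.04e-20, and adjusted p = 0.127 with an estimated correlation). Lyz2 rose from 16421 ± 719 to 35015 ± 2555, and Csf1r and Mrc1 by 0.86 ± 0.09 and 1.55 ± 0.10. Of 20 interferon response genes, 15 rose and 5 did not pass (16 rose adjusted over the list alone). The median was 0.96 (camera adjusted p = 1.44e-16, and adjusted p = 0.127 with an estimated correlation). Ifit1, Oasl2 and Isg15 rose by 2.00 ± 0.15, 1.97 ± 0.17 and 1.48 ± 0.15. Of the 841 genes that rose, 212 (25.2%) followed the leukocyte markers in both steps between groups. Of 15 epithelial, lung, mesothelial and adipose markers, 3 rose, 8 fell and 4 did not pass (4 and 9 adjusted over the list alone). The median was -1.15 (camera adjusted p = 0.000959, and adjusted p = 0.214 with an estimated correlation). The mesothelial genes Upk1b, Lrrn4, Upk3b and Msln changed by -1.68 ± 0.11, -1.53 ± 0.15, -1.38 ± 0.14 and -1.27 ± 0.11. Of 5 skeletal and cardiac muscle markers 2 fell and 3 did not pass (3 fell adjusted over the list alone). The median was -0.69 (camera adjusted p = 0.00422, and adjusted p = 0.480 with an estimated correlation). Among 16 endothelial markers, 2 rose, 2 fell and 12 did not pass (3 and 3 adjusted over the list alone, median 0.27, mean -0.11, camera direction down, adjusted p = 0.770). Emcn fell from 172 ± 0.305 to 16.0 ± 5.69 and Flt1 by 1.26 on the log2 scale. Among 10 neural and Schwann cell markers, 2 rose, 1 fell and 7 did not pass (2 and 3 adjusted over the list alone, median -0.11, mean 0.08, camera direction down, adjusted p = 0.690). The 10 sex-linked markers, 32 ribosomal protein genes and 13 mitochondrial transcripts did not pass (camera adjusted p = 0.494, 0.494 and 0.682, medians -0.06, -0.03 and -0.07).

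The 10 largest increases in heterozygous over wildtype were led by the matrix protease Mmp3 (121 ± 18.5 to 1340 ± 75.4, 3.47 ± 0.19) and held the acute phase genes Serpina3n (3.01 ± 0.13), Lbp (2.79 ± 0.27) and Hp (2.76 ± 0.19), besides Fhl5 (2.85 ± 0.31), F5 (2.69 ± 0.31), Comp and Igf2. Egfl6 (3.14 ± 0.49) was among them and did not pass without heterozygous replicate 1 (adjusted p = 0.0860) or heterozygous replicate 2 (0.0563) in a range of 1.29e-09 to 0.0860 over 17 alternatives. They also held Clec11a (3.10 ± 0.36), whose log2 change was 3.71 without wildtype replicate 1 and 2.49 without wildtype replicate 2. The largest decreases besides Emcn, Des and Kcnmb1 were those of Folh1 (-2.63 ± 0.24), Xirp2 (-2.40 ± 0.29), Vat1l (-2.25 ± 0.16), Alx4 (-2.04 ± 0.15), Ccdc81 (-1.97 ± 0.25), Mcam (-1.89 ± 0.10) and Hoxc10 (-2.05 ± 0.38). Hoxc10, the 1 of 24 Hox genes that fell (1 adjusted over the list alone, median -0.04, camera adjusted p = 0.218), did not pass without heterozygous replicate 2 (adjusted p = 0.101), wildtype replicate 1 (0.118) or wildtype replicate 2 (0.124), in a range of 1.51e-05 to 0.124 over 18 alternatives.

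In total 1274 of 15781 genes passed in heterozygous against wildtype, 841 higher and 433 lower, of which 331 and 131 changed at least 2-fold (unadjusted p under 0.05 for 2918). The 2 groups were apart in 54.8% of genes, where chance gives 33.3% under the same assumption, and 1089 of the 1137 genes called in the authors' deposited table among those tested here were shared. The count was 2996 without knockout replicate 1, 3013 without knockout replicate 2, 320 without heterozygous replicate 1, 348 without heterozygous replicate 2, 368 without wildtype replicate 1 and 419 without wildtype replicate 2, and 3032 with the knockout libraries out of the fit. Cre again differed between the groups, and the 2 alternatives chosen after seeing the data gave 990 genes without the genes that followed the leukocyte markers and 1222 (808 higher) without chromosomes X and Y.

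The comparison of knockout with heterozygous, both with Cre, asked what the loss of the remaining Jag1 allele adds. Y-linked transcripts were nearly missing from the knockout libraries alone, so a difference in sex cannot be told apart from that loss. Sox9 and Sox6 rose, and 22 of 22 leukocyte markers and 17 of 20 interferon genes fell, though with an estimated correlation neither list passed (adjusted p = 0.0617 for both). Sox9 rose from 201 ± 19 to 366 ± 139 (0.81 ± 0.22, adjusted p = 0.0458, n = 2 per group), and Sox6 from 41.9 ± 3.72 to 255 ± 6.31 (2.58 ± 0.21). The log2 change of Sox9 was 0.41 (adjusted p = 0.0426) without knockout replicate 1 and 1.21 (8.97e-08) without knockout replicate 2, so its size rested mainly on knockout replicate 1. The call on Sox9 was lost without heterozygous replicate 1 (adjusted p = 0.181), heterozygous replicate 2 (0.295), wildtype replicate 1 (0.0946) or wildtype replicate 2 (0.0943), and over 19 alternatives its adjusted p ran from 8.97e-08 to 0.295. Among those, it was also lost with no filter on low values (0.0509), with a mean of 50 or more (0.0516), without limma's mean trend (0.149), with the wildtype libraries out of the fit (0.0924) and without the genes that followed the leukocyte markers (0.0578). The authors' deposited table gave Sox9 an adjusted p of 0.339 in this comparison.

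Of 19 chondrogenic transcription factors, 4 rose, 2 fell and 13 did not pass in knockout against heterozygous (4 and 2 adjusted over the list alone, median 0.23, camera adjusted p = 0.0807, with 0.0146 without knockout replicate 2 and 0.0226 without heterozygous replicate 2 in a range of 0.0146 to 0.751 over 13 alternatives). Pax1 and Runx3 rose by 1.08 ± 0.17 and 2.38 ± 0.34. Of 20 cartilage matrix genes, 6 rose, 4 fell and 10 did not pass (7 and 5 adjusted over the list alone, median 0.11, camera adjusted p = 0.358). Pcolce2 rose by 0.95 ± 0.13 and Col2a1 from 144 ± 13.2 to 254 ± 25.5 (0.81 ± 0.16, adjusted p = 0.00874), and Acan fell from 54.2 ± 13.7 to 18.8 ± 4.15 (-1.47 ± 0.38, adjusted p = 0.0329). Without heterozygous replicate 1 or heterozygous replicate 2 neither passed (adjusted p = 0.0578 and 0.115 for Col2a1, in a range of 0.000296 to 0.115, and 0.2802 and 0.104 for Acan, in a range of 0.00256 to 0.2802). Acan also did not pass with no filter on low values (adjusted p = 0.0514), with quantile normalization (0.0530) or without the mean trend (0.0699). Of 13 genes of hypertrophic cartilage and bone, 3 rose, 5 fell and 5 did not pass (4 and 5 adjusted over the list alone, median -0.01, camera adjusted p = 0.273, with 0.0351 without knockout replicate 1 in a range of 0.0351 to 0.751). Col10a1, Mmp13 and Mgp changed by -1.20 ± 0.12, -1.67 ± 0.15 and -0.87 ± 0.09, and Mmp9 by -4.63 ± 0.53, which was -5.68 without knockout replicate 1 and -3.59 without knockout replicate 2. Of 10 tendon and sclerotome genes 1 rose, 2 fell and 7 did not pass (2 and 3 adjusted over the list alone, median -0.19, camera adjusted p = 0.512).

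Of 39 contractile smooth muscle genes, 2 rose, 11 fell and 26 did not pass in knockout against heterozygous (6 and 14 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.00828, and adjusted p = 0.751 with an estimated correlation). Myosin light chain kinase Mylk fell from 4886 ± 57.8 to 1968 ± 222, and Actg2 and Mrvi1 changed by -0.95 ± 0.08 and -0.99 ± 0.12. The list's call was lost without knockout replicate 2 (adjusted p = 0.369), in a range of 7.71e-06 to 0.751 over 13 alternatives. Of 33 interstitial collagens and small proteoglycans, 4 rose, 13 fell and 16 did not pass (4 and 13 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.000644, and adjusted p = 0.751 with an estimated correlation). Lum fell by 2.00, and Col15a1, Dcn, Postn and Col3a1 changed by -2.28 ± 0.12, -1.94 ± 0.11, -1.30 ± 0.09 and -0.86 ± 0.09. Of those 13 lower genes, 5 followed the leukocyte markers, which fell too. Of 18 fibroblast and adventitial markers, 1 rose, 8 fell and 9 did not pass (1 and 9 adjusted over the list alone). The median was -0.86 (camera adjusted p = 0.000625, and adjusted p = 0.539 with an estimated correlation). Dpt fell from 254 ± 7.23 to 65.3 ± 2.49 and Dlk1 rose from 680 ± 45.6 to 2536 ± 470. Of 24 elastic fibre genes, 4 rose, 7 fell and 13 did not pass (4 and 10 adjusted over the list alone, median -0.21, camera adjusted p = 0.0828, with 0.00197 without knockout replicate 1 in a range of 0.00197 to 0.751). Efemp1 rose by 1.17 ± 0.08, and Mfap4, Fbln1 and Loxl2 changed by -1.57 ± 0.15, -1.35 ± 0.13 and -0.63 ± 0.08.

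Of 34 proliferation genes, 7 rose, 0 fell and 27 did not pass in knockout against heterozygous (13 and 0 adjusted over the list alone). The median was 0.27 (camera adjusted p = 9.70e-08, and adjusted p = 0.0617 with an estimated correlation). Rrm2 rose by 0.61 ± 0.09. Of 13 Notch targets 2 rose and 11 did not pass (3 rose adjusted over the list alone, median 0.29, camera adjusted p = 0.101, with 0.0194 without knockout replicate 2 in a range of 0.0194 to 0.751 over 13 alternatives), and Ccnd1 rose by 0.66 ± 0.08. Of 30 Notch ligands, receptors and modifiers 1 rose, 2 fell and 27 did not pass (1 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.156, with 0.0267 without knockout replicate 1 in a range of 0.0267 to 0.751). Jag1 itself was 1 of the 2 ligands, receptors and modifiers that fell. In TGF-beta and BMP signalling 4 of 36 genes rose, 4 fell and 28 did not pass (6 and 7 adjusted over the list alone, median -0.04, mean 0.02, camera direction down, adjusted p = 0.798), with Smad9 up by 0.80 ± 0.10. In Wnt signalling 4 of 25 rose, 8 fell and 13 did not pass (5 and 8 adjusted over the list alone, median -0.21, camera adjusted p = 0.296), with Lgr6 up by 1.74 ± 0.19 and Sfrp1 down from 7519 ± 142 to 2044 ± 255. The 10 Hedgehog genes did not pass (median -0.01, mean 0.01, camera direction up, adjusted p = 0.594). Of 27 immediate early genes, 8 fell and 19 did not pass (8 fell adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.0289, and adjusted p = 0.751 with an estimated correlation). Atf3 fell by 2.07 on the log2 scale, and the list's call was lost without knockout replicate 2 (adjusted p = 0.771) or heterozygous replicate 1 (0.0593), in a range of 2.23e-07 to 0.771. Of 24 hypoxia and glycolysis genes 1 rose, 5 fell and 18 did not pass (1 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.322), with Vegfa at -0.67 ± 0.09.

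All 22 macrophage and leukocyte markers fell in knockout against heterozygous (22 adjusted over the list alone). The median was -2.31 (camera adjusted p = 2.20e-33, and adjusted p = 0.0617 with an estimated correlation). Lyz2 fell from 35015 ± 2555 to 6937 ± 287, and C1qa, Csf1r and Mrc1 changed by -2.49 ± 0.19, -1.88 ± 0.09 and -2.78 ± 0.10. Of 20 interferon response genes, 17 fell and 3 did not pass (18 fell adjusted over the list alone). The median was -2.38 (camera adjusted p = 6.11e-23, and adjusted p = 0.0617 with an estimated correlation). Isg15, Usp18 and Oasl2 changed by -3.20 ± 0.15, -3.15 ± 0.18 and -3.24 ± 0.17. Of the 1276 genes that fell, 430 (33.7%) lay in the span of the leukocyte markers, which Cx3cr1 widened. Among them were 8 of the 17 interferon genes. Among 15 epithelial, lung, mesothelial and adipose markers, 7 rose, 1 fell and 7 did not pass (7 and 2 adjusted over the list alone). The median was 0.51 (camera adjusted p = 0.00155, and adjusted p = 0.206 with an estimated correlation). Lrrn4, Msln and Upk1b rose by 1.58 ± 0.15, 1.18 ± 0.11 and 0.99 ± 0.11. Among 16 endothelial markers 1 rose, 4 fell and 11 did not pass (1 and 4 adjusted over the list alone, median -0.19, camera adjusted p = 0.232), with Kdr at 0.94 ± 0.12 and Flt1 at -1.21 ± 0.11. Among 10 neural and Schwann cell markers 2 rose, 2 fell and 6 did not pass (2 and 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.358), with Stmn2 up from 58.3 ± 7.64 to 594 ± 43.9. Of 24 Hox genes 4 rose and 20 did not pass (7 rose adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.00722, and adjusted p = 0.751 with an estimated correlation), a call lost without knockout replicate 1 (adjusted p = 0.462) in a range of 7.27e-07 to 0.751 over 13 alternatives. Of 5 skeletal and cardiac muscle markers 1 rose and 4 did not pass (2 rose adjusted over the list alone, median 0.18, camera adjusted p = 0.496).

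**Figure D3:**
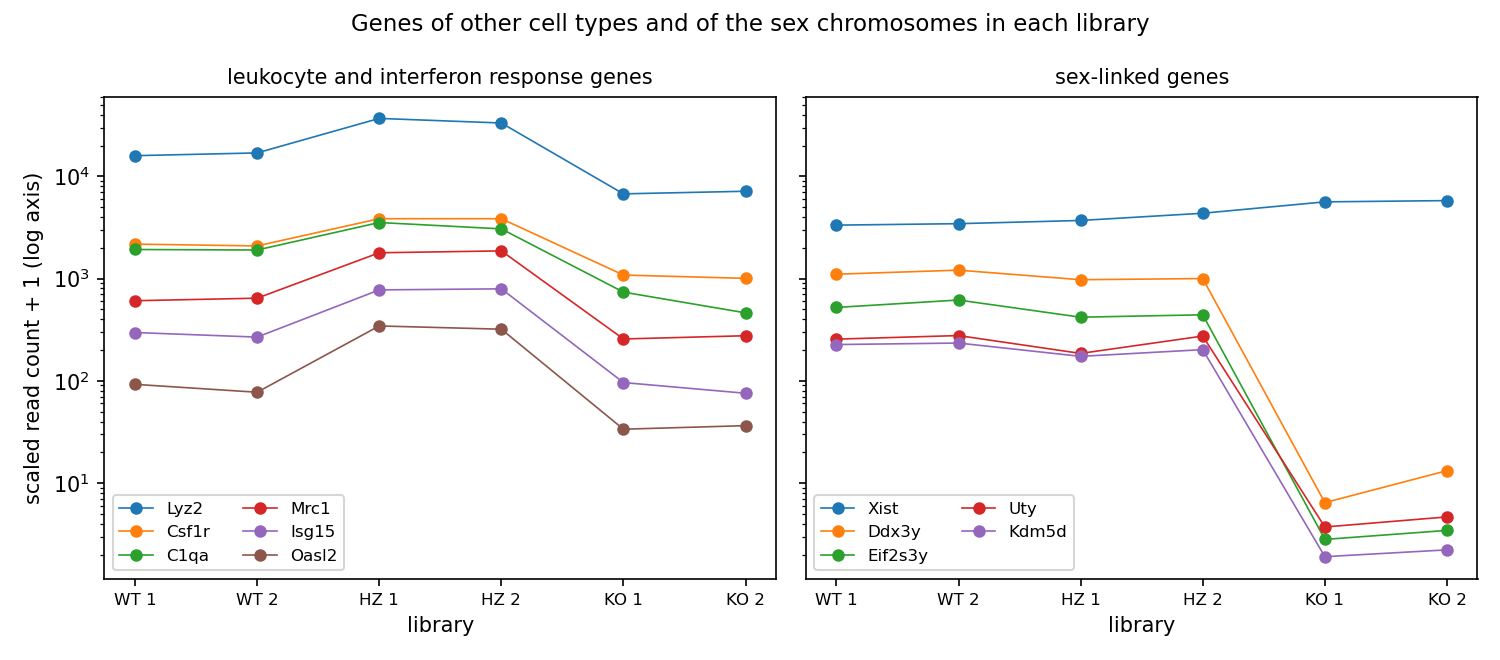
Scaled read count + 1 on a log axis (y) in each of the 6 libraries (x) for leukocyte and interferon response genes (left) and sex-linked genes (right); lines join the values of a gene. Lyz2 averaged 16421 in wildtype, 35015 in heterozygous and 6937 in knockout, and Ddx3y averaged 1155, 986 and 8.83.

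Of the 10 sex-linked markers, 2 rose, 4 fell and 4 did not pass in knockout against heterozygous (4 and 4 adjusted over the list alone, median 0.18, mean -2.38, camera direction down, adjusted p = 0.259, with 0.0267 without knockout replicate 1 in a range of 0.00253, from fry, to 0.751 over 13 alternatives). Eif2s3y, Ddx3y and Uty changed by -7.11 ± 0.19, -6.74 ± 0.27 and -5.76 ± 0.24, and the 2 knockout reads of Kdm5d were 0.564% of its heterozygous level (exact 95% interval 0.0680% to 2.05%, counting error only). Besides Stmn2, Sox6 and Runx3, the 10 largest increases included those of S100a7a (2.85 ± 0.26), Irx5 (2.47 ± 0.24), Prl2c3 (2.45 ± 0.17), Irx3 (2.35 ± 0.28), Crabp1 (2.14 ± 0.25) and Pkp1 (2.17 ± 0.42), of which Pkp1 did not pass without heterozygous replicate 2 (adjusted p = 0.0949, in a range of 0.000588 to 0.0949 over 18 alternatives). Prl2c3 has near-identical copies, so its reads are uncertain. Besides Jag1, Mmp9 and the Y-linked genes, the 10 largest decreases included those of the interferon-induced Oas2 (-4.56 ± 0.41) and the chemokines Cxcl9 (-4.37 ± 0.45) and Ccl6 (-4.37 ± 0.15). The ribosomal protein genes had 1 higher member of 32 (0 adjusted over the list alone, median -0.06, camera direction up, adjusted p = 0.798), and the 13 mitochondrial transcripts did not pass (median 0.11, camera adjusted p = 0.358).

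In total 1968 of 15781 genes passed in knockout against heterozygous, 692 higher and 1276 lower, of which 177 and 719 changed at least 2-fold (unadjusted p under 0.05 for 4006). With the wildtype libraries out of the fit, 1385 passed. The 2 groups were apart in 50.4% of genes, where chance gives 33.3% under the same assumption, and 1497 of the 1514 genes called in the authors' deposited table among those tested here were shared. The count was 3283 without knockout replicate 1, 5673 without knockout replicate 2, 817 without heterozygous replicate 1 and 877 without heterozygous replicate 2. The 2 alternatives chosen after seeing the data gave 1366 genes without the genes that followed the leukocyte markers and 1900 without chromosomes X and Y.

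The changes of both groups against wildtype were set side by side. Among the genes called in both, 258 were higher in both, Comp, Dlk1 and Col2a1 among them, and 238 were lower in both, Des, Loxl2 and Vegfa among them. The knockout was lower and the heterozygous group higher for 262 genes, such as Lyz2 and Isg15, and the reverse held for 8. These counts depended on each library: those in the same direction, 496 in all, were 1086 without knockout replicate 1, 1222 without knockout replicate 2, 152 and 158 without heterozygous replicate 1 or 2, and 135 and 163 without wildtype replicate 1 or 2, fits chosen after seeing the data. Independent lists of the same sizes would give 45.6, 30.8, 59.7 and 23.5. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.252, where unchanged groups simulated against the same wildtype libraries gave 0.480, and their covariance was 0.0578 against 0.0282 simulated, a difference of 0.0295. Those simulated groups, which hold no effects, gave on average 0.02 genes higher in both (at most 1) and 0 lower in both. The 2 wildtype libraries were too few to split, so part of the excess of shared calls may come from the shared controls. Cre was present in both other groups and not in wildtype, so its effect on shared calls cannot be told apart from that of Jag1. The shared calls come from fits without the replicate number as a block.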

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

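All tests in this part were chosen only after the results were seen. By their medians the leukocyte and interferon lists were lower in knockout and higher in heterozygous than in wildtype, and -2.31 and -2.38 in knockout over heterozygous, but with an estimated correlation neither passed (adjusted p = 0.0722 and 0.115 in knockout over wildtype, 0.127 for both in heterozygous over wildtype and 0.0617 for both in knockout over heterozygous), and 3 of 22 and 5 of 20 members, Cx3cr1 (-0.40) among them, did not pass in heterozygous over wildtype. A different share of leukocytes between the groups may account for the leukocyte markers, because 94.7% of 19 members lay within 0.6 of their common median in knockout over heterozygous. In heterozygous over wildtype, where this was not tested, the 19 ran from -0.40 to 1.55 around a median of 0.87. The list's median differed by at most 0.0898 between libraries of a group. Those values were already scaled for depth, so this shows only that no effect of depth was left within a group. Of 16 interferon genes, 4 lay beyond the leukocyte range by over 2 SE: Isg15 (-3.20), Oasl2 (-3.24) and Usp18 (-3.15) below its low end of -2.78 in knockout over heterozygous, and Ifit1 (2.00, with -2.88 in knockout over heterozygous) above its high end of 1.55 in heterozygous over wildtype. Because 2 members of the leukocyte list with lower values, Aif1 (-4.23 in knockout over heterozygous) and Cd74 (3.18 in heterozygous over wildtype), also lay beyond it, the range does not bound what leukocytes give, and 8 of the 12 other interferon members lay inside it, so for all 16 a share of leukocytes and a change within cells cannot be told apart. Leukocytes of another kind or state, and an effect of Cre or of Jag1 on them, stay open and were not tested.

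Both knockout libraries were nearly without Y-linked transcripts, the highest called gene being at 1.203% of wildtype, and Xist was highest in them. The knockout samples may thus have come from female embryos, which the labels do not state. The wildtype libraries held much Xist as well as Y-linked transcripts, and none of 10 sex-linked markers passed in heterozygous against wildtype. Wildtype and heterozygous samples may thus have held cells of both sexes. For 496 knockout calls the heterozygous libraries had a call in the same direction, a number that moved with each library left out. Those libraries had no such loss of Y-linked transcripts, the lowest of these genes being at 75.6% of wildtype. This does not exclude sex for the knockout calls, because another cause could have made the heterozygous calls of the same genes. For these and the other 1481 calls of knockout against wildtype, sex and genotype cannot be told apart. The same holds for the 1968 calls of knockout against heterozygous, because both knockout libraries nearly lacked Y-linked transcripts.

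Jag1 in the heterozygous libraries was at 28% of wildtype, and its log2 change of -1.84 lay below the -1 of a single lost allele by more than 2 SE (95% interval -2.35 to -1.33). Loss of 1 allele alone was thereby excluded under the fitted error. The lower quartile of the contractile genes was -0.463, short of the -0.842 by which Jag1 exceeded 1 allele. Those genes did not move together, since Des and Kcnmb1 fell by more than that excess and Mylk hardly changed. Their quartile thus does not bound dilution by other cells, which stays open. Lower transcription of the remaining allele, recombination of it and an effect of Cre stay open and were not tested.

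Other genes that passed in opposite directions against wildtype had these log2 values of knockout over heterozygous: Lyz2 -2.33, C1qa -2.49, Csf1r -1.88, Mrc1 -2.78, Cxcl9 -4.37, Ccl6 -4.37, Dcn -1.94, Sfrp1 -1.88, Hp -4.00, C3 -3.66 and Atf3 -2.07.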

How the results depend on the processing

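The alternatives without genes on chromosomes X and Y and without genes that follow the leukocyte markers were chosen only after the results were seen; the others were set beforehand, apart from those of the shared count given last. Of 210 named gene results, 205 passed, and 192 of these kept their call and direction under every alternative run. Of 78 list results, 28 passed, and 21 of these kept their call without each library in turn. None of the 28 passed with an estimated correlation in camera. The cause of these differences was not tested. Most named genes were picked for large changes or small p values in these data, so their stability does not stand for that of all calls.

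With an estimated correlation, the lists that had passed in knockout against wildtype had adjusted p values of chondrogenic factors 0.712, cartilage matrix 0.343, contractile 0.673, collagens 0.673, proliferation 0.0722, hypoxia 0.712, interferon 0.115 and leukocyte 0.0722. With an estimated correlation, the lists that had passed in heterozygous against wildtype had adjusted p values of chondrogenic factors 0.723, cartilage matrix 0.214, hypertrophic cartilage 0.214, contractile 0.480, Wnt 0.671, hypoxia 0.653, interferon 0.127, leukocyte 0.127, fibroblast 0.214, skeletal muscle 0.480 and epithelial 0.214. With an estimated correlation, the lists that had passed in knockout against heterozygous had adjusted p values of contractile 0.751, collagens 0.751, proliferation 0.0617, immediate early 0.751, interferon 0.0617, leukocyte 0.0617, fibroblast 0.539, epithelial 0.206 and Hox 0.751.

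With fry, lists that no longer passed were chondrogenic factors 0.0665 (knockout against wildtype), chondrogenic factors 0.266, contractile 0.0801, Wnt 0.132, hypoxia 0.112 and skeletal muscle 0.0833 (heterozygous against wildtype), contractile 0.111, immediate early 0.289 and Hox 0.406 (knockout against heterozygous). Lists that passed with fry and not with camera at the preset correlation were hypertrophic cartilage 0.0426, neural 0.0280 and sex-linked 0.00196 (knockout against wildtype), proliferation 0.0326 (heterozygous against wildtype), neural 0.0217 and sex-linked 0.00253 (knockout against heterozygous). Lists that had not passed and turned direction were tendon 0.493 and fibroblast 0.849 (knockout against wildtype), ribosomal 0.979 (knockout against heterozygous). With quantile normalization, Notch ligands 0.0374 and elastic fibre 0.0374 (heterozygous against wildtype), elastic fibre 0.0102 (knockout against heterozygous) passed, and fibroblast 0.826 (knockout against wildtype), mitochondrial 0.604 (heterozygous against wildtype), ribosomal 0.588 (knockout against heterozygous) turned direction without passing. A pseudocount of 8 turned fibroblast 0.940 (knockout against wildtype). With the replicate number as a block, Hedgehog passed in heterozygous against wildtype (0.0496) and the uncalled fibroblast list turned in knockout against wildtype (0.958); the block gave 2487, 1572 and 2510 genes in the 3 comparisons and changed no other call of a list or named gene.

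Leaving out each library in turn gave 865 to 5613 genes in knockout against wildtype, 320 to 3013 in heterozygous against wildtype and 817 to 5673 in knockout against heterozygous, and with only the 2 groups compared heterozygous against wildtype had 3032. In the fits of only the 2 groups compared, knockout against wildtype had 1367 genes and knockout against heterozygous 1385. With each library left out in turn, the log2 change of Hes1 in knockout against wildtype ran from -0.0901 to 0.216. That of Acan ran from -0.26 to 0.65, with -0.02 without knockout replicate 1. Adjusted p values of lists that changed call or direction in knockout against wildtype ran over the fits without 1 library as follows: chondrogenic factors 0.000147 to 0.0944, tendon 0.355 to 0.974, Notch targets 0.171 to 0.912, Notch ligands 0.411 to 0.924, elastic fibre 0.146 to 0.906, Hedgehog 0.00435 to 0.478, Wnt 0.291 to 0.959, immediate early 1.30e-06 to 0.632, hypoxia 0.00717 to 0.0916, fibroblast 0.757 to 0.976, skeletal muscle 0.0197 to 0.372, Hox 5.46e-05 to 0.970, sex-linked 0.0233 to 0.306, ribosomal 0.273 to 0.906 and mitochondrial 0.153 to 0.970. Adjusted p values of lists that changed call or direction in heterozygous against wildtype ran over these fits as follows: chondrogenic factors 0.0139 to 0.141, Notch ligands 0.0490 to 0.188, elastic fibre 0.0475 to 0.303, Hedgehog 0.0225 to 0.292, immediate early 0.0853 to 0.926, hypoxia 0.00281 to 0.141, endothelial 0.202 to 0.989, sex-linked 0.145 to 0.851, ribosomal 0.0789 to 0.765 and mitochondrial 0.162 to 0.726. Adjusted p values of lists that changed call or direction in knockout against heterozygous ran over these fits as follows: chondrogenic factors 0.0146 to 0.501, hypertrophic cartilage 0.0351 to 0.411, contractile 7.71e-06 to 0.369, Notch targets 0.0194 to 0.456, Notch ligands 0.0267 to 0.667, elastic fibre 0.00197 to 0.376, TGF-beta 0.462 to 0.883, Hedgehog 0.149 to 0.696, immediate early 2.23e-07 to 0.771, Hox 7.27e-07 to 0.462, sex-linked 0.0267 to 0.301 and ribosomal 0.102 to 0.837. Genes past the threshold in the same direction in both comparisons against wildtype, a count refitted without each library after seeing the data, were 496, with 1086 and 1222 without knockout replicate 1 or 2, 152 and 158 without heterozygous replicate 1 or 2, and 135 and 163 without wildtype replicate 1 or 2.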

Other observations

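The tests of this part and its genes were chosen only after the values were seen. Igf2 and H19, neighbouring imprinted genes of fetal growth, were both highest in the heterozygous libraries. Igf2 measured 1785 ± 15.2 in wildtype, 11719 ± 225 in heterozygous and 3041 ± 913 in knockout libraries, and H19 2151, 8673 and 3523. The log2 changes of heterozygous over wildtype were 2.71 ± 0.17 and 2.01 ± 0.18, and those of knockout over heterozygous -1.98 ± 0.17 and -1.34 ± 0.18. The other imprinted growth genes, without Dlk1, which rose from 197 to 680 in heterozygous over wildtype (1.79 ± 0.14), did not move with them as a list: of 24, 1 rose and 3 fell in heterozygous over wildtype with a median of -0.21 (limma camera p = 0.00159, and p = 0.0394 with an estimated correlation), 8 rose and 1 fell in knockout over heterozygous with a median of 0.10 (0.0113 and 0.0673), and 4 rose and 4 fell in knockout over wildtype with a median of -0.03 (0.958).

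Several acute phase and matrix-degrading genes were highest in the heterozygous libraries too, while Hp, Lbp and C3 were lowest in knockout and Mmp3, Serpina3n and Ptx3 in wildtype. Mmp3 measured 121, 1340 and 198 in wildtype, heterozygous and knockout libraries, Serpina3n 157, 1272 and 169, Hp 96.0, 663 and 40.4, Lbp 25.8, 180 and 19.4, C3 138, 589 and 45.6, and Ptx3 191, 836 and 226. Of 21 other acute phase and inflammatory genes, 8 rose and 0 fell in heterozygous over wildtype with a median of 0.43 (limma camera p = 2.48e-05, and p = 0.0191 with an estimated correlation), and 2 rose and 13 fell in knockout over heterozygous with a median of -1.25 (2.66e-08 and 0.00887). In knockout over wildtype 4 rose and 7 fell, with a median of -0.41 (0.00978 and 0.0662).

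Leukocytes transcribe part of these genes, so the share of leukocytes may contribute to the acute phase genes. In knockout over heterozygous 94.7% of 19 leukocyte markers lay within 0.6 of a common shift. Igf2 and H19 rose by more than the highest of the 19 leukocyte markers in heterozygous over wildtype (1.55), and their means lay above wildtype in knockout, where the leukocyte median was -1.39. Those ends do not bound what leukocytes give, so the explanation of the 2 genes stays open. An inflamed or differently dissected tissue in the heterozygous samples is another candidate explanation, which was not tested.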
